A study of Mus musculus with 12 samples.

How the data were processed

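The data are 12 Affymetrix mouse expression arrays, hybridised with RNA of C4-HD mammary carcinomas from BALB/c mice. Per the labels' protocols, the tumours had been fixed in formalin and embedded in paraffin, their RNA was purified with the RNeasy FFPE kit, and 200 ng went into each labelling. Per the submitters' processing notes the arrays were processed with GCRMA, a background correction and summary method, whose version is not given in the sources used here. The deposited values are on a log2 scale: 45101 probe sets in 12 columns.

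The values were checked before any test was chosen. For 45099 of the 45101 probe sets the linear values of the 2 MPA arrays average 1 within a tolerance of 0.0001, so that the deposited log2 value is a ratio to the linear mean of the MPA arrays. The smallest linear value is 0.01, reached in 3 cells. Differences between arrays are kept by this step, while the level of a probe set above background is lost. The mean of the log2 values in MPA lies below 0 for genes that vary there, and far below it for some genes of other organs, such as Ttr (-2.68), Alb (-1.95) and Cyp2e1 (-1.17). Their fold changes against MPA are larger by these amounts than their ratios to the linear MPA mean. The columns' medians are 0.01 and -0.01 for MPA, -0.01 and 0.00 for no MPA, 0.00 and 0.01 for MFP 6 h, 0.00 and 0.00 for MFP 12 h, -0.02 and -0.11 for MFP 24 h, and -0.04 and -0.03 for MFP 48 h. Replicates were compared before averaging: the SD of the difference between the arrays of a group was 0.39 to 0.56 over the probe sets, and no pair was identical. Only the ratios were used, and the scanner's own values were not used here, so signal over background is unknown for each gene.

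The design written before the data were examined had a filter on log2 values above 5 and took the probe set with the highest mean for each gene. Neither has a meaning for ratios. In their place all genes were tested. The probe set with the largest SD over all 12 arrays, taken without regard to group, stood for its gene. This SD includes differences between groups. Where a gene has several probe sets, the rule thus favours those with larger changes. Of the probe sets 34945 have 1 gene symbol in the platform annotation, 932 have several, and 9160 others have none here, besides 64 controls. Only those with 1 symbol were used, giving 18193 genes, of which 9010 have more than 1 probe set. Probe sets of one gene can disagree: of the 9 for H2-D1, 1 was called in the opposite direction at MFP 48 h. The array cannot tell near-identical members of gene families apart. Of the 465 list members 39, among them Areg, were not analysed here.

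Groups were taken from the source names of the labels. Tests used limma 3.58.1 in R 4.3.3: 1 model with a mean for each of the 6 groups over all 12 arrays, contrasts between groups, moderated variances (eBayes, 6 residual and 4.21 prior degrees of freedom), and Benjamini-Hochberg adjustment over all genes at 0.05. Sharing the spread over the groups was chosen because each has 2 arrays. The 7 contrasts were each MFP time, the mean of the 4 MFP times and no MPA against MPA, and MFP 48 h against no MPA. The time trend is the slope on the log2 of hours in the 8 MFP arrays. The 27 gene lists, fixed before the data were examined, were tested with camera at its preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals. No list that was called with the preset correlation was called with the estimated one, in any of the contrasts or the trend. An adjusted p of a gene is limma's over all genes tested; the count adjusted over the list alone uses the list's own genes.

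Named genes followed a rule fixed before the data were examined: the 6 largest rises and the 6 largest falls among the genes past the threshold whose arrays did not overlap between the groups, up to 2 list members per direction that passed, the member with the smallest p where none did, and a set named in every comparison (Pgr, Esr1, Tnfsf11, Wnt4, Ccnd1, Mki67, Cdkn1a, Krt8 and Fkbp5). Part of each is printed. Lists of liver, exocrine pancreas, islet, kidney, intestine, epidermis, heart, brain, ribosome biogenesis and nucleotide synthesis genes were written from textbook knowledge after the largest changes had been seen (of 27 liver genes 0 and of 20 pancreas genes 1, Cel, are also in a list fixed before; how far the carcinoma itself expresses them cannot be read from ratios), and contrasts between successive MFP times were also added then.

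The scripts were tested on simulated data of 18193 genes with the residual spread of the real ones and 200 changed genes in each of 10 simulations. For MFP 48 h versus MPA, 20.8% of changes of 1 on the log2 scale, 91.8% of 2 and 98.7% of 3 were recovered, and 6.51% of the calls were false. For the time trend with the same total changes from 6 h to 48 h these shares were 22.9%, 92.0% and 98.5%, with 4.72% false. In the unchanged comparison of no MPA with MPA no gene was called. A list of mitotic genes lowered by 1 was called in its simulation with both correlations, and none of the other lists was. The simulated genes varied independently of each other. The simulation therefore does not show how either correlation setting behaves where genes of a list vary together.

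Alternatives were every probe set on its own, centring of each array on its median, a fit of the compared groups alone, array weights, each array left out in turn, and, added after seeing the data, the mean of a gene's probe sets, the more variable genes only, a robust prior, genes that do not follow the liver, pancreas or muscle genes, and a fit without the MFP 24 h arrays. Comparisons that share the MPA arrays were set against 100 simulations of unchanged groups and, after seeing the data, recomputed with 1 MPA array for each.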

Results

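Gene expression was measured in C4-HD, a mouse mammary carcinoma that was grown in BALB/c mice given MPA, a progestin. When tumours reached an area of 50 mm2 the MPA pellet was taken out and a pellet of MFP (mifepristone, an antagonist of the progesterone receptor, 10 mg/kg/day) was put in. A contrast of MFP with MPA thus changes both at once, and a group labelled as without MPA was measured at 48 h only. The 12 arrays fell into 6 groups of 2: tumours with MPA, tumours 48 h after saline and labelled as without MPA, and tumours at 6 h, 12 h, 24 h and 48 h of MFP. The times are those of the sample labels: the series text names 12 h, 24 h and 48 h but no 6 h group, and also has the tumours taken out after 2 days. The 6 h group and the time axis of the trend rest on the labels. RNA came from formalin-fixed, paraffin-embedded tissue. The number of arrays limits the precision of every value. The series text calls the arrays of a group independent replicates, and no label ties them to separate animals, so p-values measure the spread between these samples. Each value is a log2 ratio to the mean of the MPA arrays, and each ± after a log2 fold change is its standard error in limma with n = 2 arrays per group. A list is said to be lower or higher where camera called it.

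The labels of the MPA and no MPA groups leave an ambiguity: the treatment protocol describes saline-treated tumours with MPA as the control, while the saline-treated arrays carry the source name without MPA. The group is called no MPA here, after its source name. The ratio of 3' to 5' control probe sets, which rises as RNA is broken, differed between groups. For Actb the 3' minus 5' difference relative to MPA averaged -0.01 ± 0.09 (SD, n = 2) in MPA, 0.02 ± 0.16 in no MPA, 0.16 ± 0.05 at 6 h, 0.35 ± 0.02 at 12 h, 0.43 ± 0.11 at 24 h and 0.53 ± 0.09 at 48 h of MFP. That of the 18S rRNA controls was 0.02 and -0.02 in the MPA arrays. It was lower in the other groups, at -0.06 in both no MPA arrays and between -0.15 and -0.06 in the MFP arrays. Genes of other organs also differed between arrays. The median over 27 liver genes was 3.50 and 3.95 in the MFP 24 h arrays, 0.74 and -1.59 in the MPA arrays, and between -1.38 and 0.95 in the others. The median over 20 exocrine pancreas genes was 5.73 and 4.24 at 6 h, 0.04 and 0.87 at 12 h, 0.74 and 6.62 at 24 h, and 4.69 and 5.27 at 48 h. The median over 15 skeletal muscle genes was 3.29 in MFP 48 h replicate 1 and at most 0.80 in any other array.

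**Figure D1:**
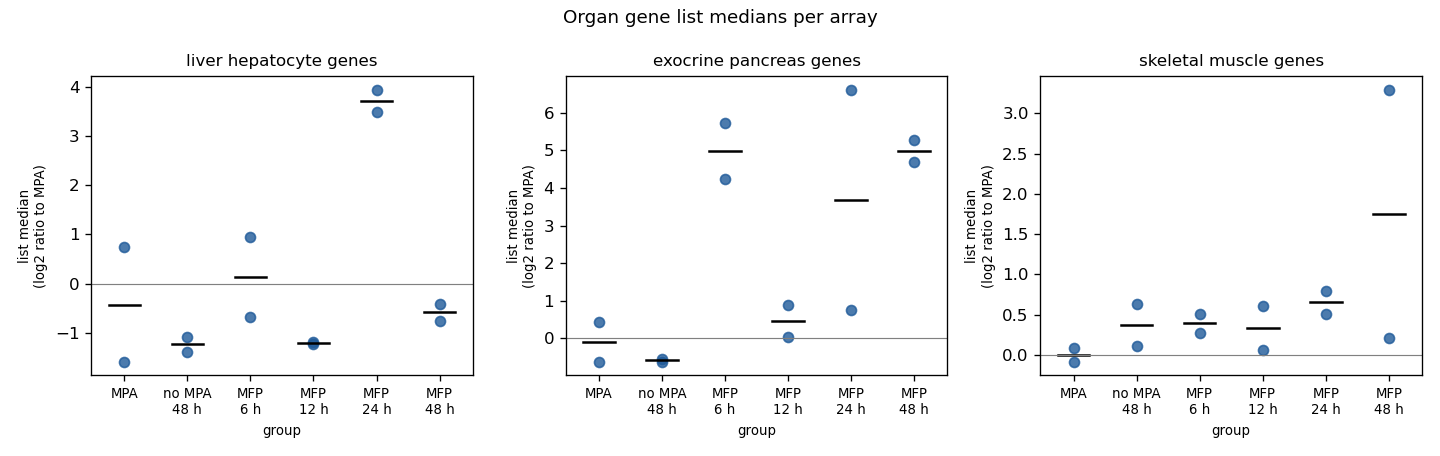
Median log2 ratio to MPA (vertical axis) of liver, exocrine pancreas and skeletal muscle genes in each group (horizontal axis). Points are single arrays and bars are group means. The liver genes stood at 3.50 and 3.95 in the MFP 24 h arrays, and the pancreas genes at 5.73 and 4.24 in the MFP 6 h arrays.

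**Figure D2:**
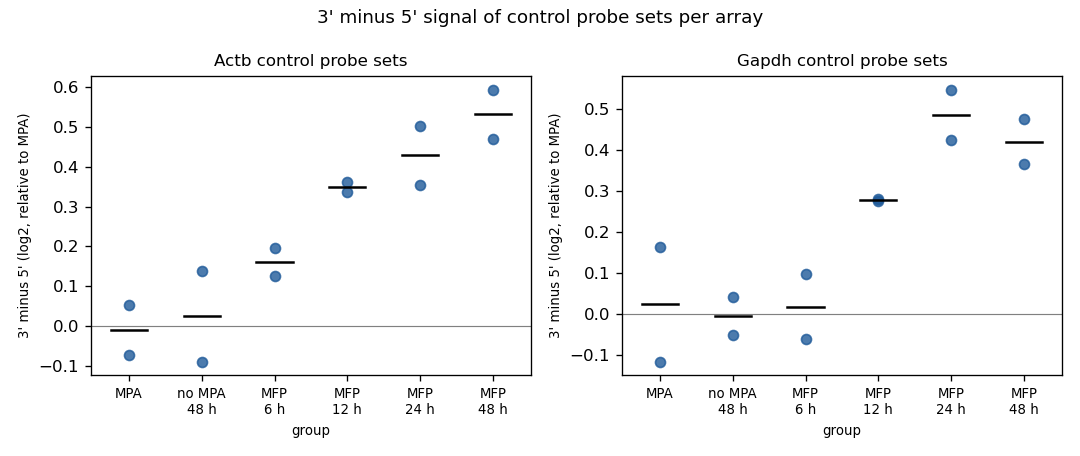
Difference of the 3' and 5' control probe sets of Actb and Gapdh (vertical axis, log2, relative to MPA) in each group (horizontal axis). Points are single arrays and bars are group means. The Actb mean rose from -0.01 in MPA to 0.53 at MFP 48 h.

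The first comparison asked how tumours at 48 h of MFP differed from tumours with MPA. Cell division genes were lower and genes of macrophages, fibroblasts and their matrix were higher. Of 24 measured DNA replication and G1/S genes 6 fell and none rose, with 15 falling when adjusted over the list alone (list median -0.84, camera adjusted p = 4.03e-08, adjusted p = 0.159 with an estimated correlation). They included Cdc6, which loads the replicative helicase (-2.83 ± 0.44, adjusted p = 0.00575), and Mcm3, part of that helicase (-1.63 ± 0.42). Of 23 mitotic genes 13 fell and none rose, with 18 when adjusted over the list alone (median -1.13, camera adjusted p = 7.59e-12, adjusted p = 0.159 with an estimated correlation). The kinase gene Aurkb (-2.68 ± 0.21), Top2a (-2.14 ± 0.40) and the proliferation marker Mki67 (-1.75 ± 0.40, adjusted p = 0.0205) were among the genes that fell, while Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 0.92 ± 0.23. Myc fell (-1.46 ± 0.29), and Ccnd1 stood at -0.53 ± 0.24 without passing the test (adjusted p = 0.176). The Actb 3' minus 5' difference was 0.53 ± 0.09 at 48 h and -0.01 ± 0.09 in MPA (SD, n = 2).

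Of 17 macrophage markers 15 rose and none fell (16 when adjusted over the list alone). The median log2 fold change of the list was 2.09 (camera adjusted p = 3.61e-13, adjusted p = 0.173 with an estimated correlation). The risen genes included the scavenger receptor Msr1 (3.86 ± 0.62) and Cd68 (2.73 ± 0.33, adjusted p = 0.00308). The list median differed between the MPA arrays, at -0.82 and 0.52, and was 1.96 and 1.95 at 48 h. Of 20 fibroblast and collagen matrix genes 17 rose and none fell (18 when adjusted over the list alone), with a median of 1.80 (camera adjusted p = 5.14e-13, adjusted p = 0.159 with an estimated correlation), among them the matrix protease Mmp2 (2.52 ± 0.51) and Postn (2.39 ± 0.25). Of 12 neutrophil markers 5 rose (7 when adjusted over the list alone; camera adjusted p = 5.60e-06, adjusted p = 0.159 with an estimated correlation), including S100a8 (4.34 ± 1.11) and Mmp8 (2.86 ± 0.25). The neutrophil median was 3.19 in MFP 48 h replicate 1, the array with muscle genes at 3.29, and 1.10 in replicate 2. Of 20 mammary involution genes 10 rose and none fell (12 and 1 when adjusted over the list alone; camera adjusted p = 5.60e-06, adjusted p = 0.159 with an estimated correlation), including Timp1 (2.68 ± 0.58) and Clu (2.57 ± 0.41). The endothelial list was higher (median 0.95, camera adjusted p = 0.00159, adjusted p = 0.173 with an estimated correlation), but its members moved both ways. Of 16 genes 5 rose, such as Emcn (1.78 ± 0.36), and Vwf fell (-1.67 ± 0.32). Adjusted over the list alone, 7 rose and 1 fell. No member of the T and NK cell list (15 genes, median 0.32) or of the B and plasma cell list (12 genes, median 0.67) passed the test, also when adjusted over the list alone. In these arrays the pancreas genes had medians of 4.69 and 5.27.

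Of 17 cholesterol and fatty acid synthesis genes 11 fell and none rose (15 when adjusted over the list alone), with a median of -1.47 (camera adjusted p = 1.51e-09, adjusted p = 0.159 with an estimated correlation). Idi1, of the isoprenoid branch, stood at -3.46 ± 0.43 and Cyp51 at -2.21 ± 0.35. Of 16 hypoxia and glycolysis genes 5 fell (6 when adjusted over the list alone; camera adjusted p = 5.60e-06, adjusted p = 0.370 with an estimated correlation), including Car9, a carbonic anhydrase (-1.43 ± 0.39). Of 11 ribosomal protein genes 4 fell (5 when adjusted over the list alone; camera adjusted p = 0.00203, adjusted p = 0.159 with an estimated correlation). Among 17 luminal epithelial markers 5 fell and 1 rose, the same numbers as when adjusted over the list alone, and the list was not called (camera adjusted p = 0.137). The transcription factor genes Gata3 (-2.18 ± 0.46), Foxa1 (-1.80 ± 0.34) and Esr1 (-1.72 ± 0.24, adjusted p = 0.00375) fell, Cldn4 rose (1.19 ± 0.23), and Krt8 stood at 0.01 ± 0.26. Of 15 basal and myoepithelial markers 3 rose (4 when adjusted over the list alone; camera adjusted p = 0.0167, adjusted p = 0.200 with an estimated correlation), including Acta2 (2.88 ± 0.64), which smooth muscle cells and activated fibroblasts also express. Its camera adjusted p was 0.0655 without MPA replicate 1 and 0.0866 without MFP 48 h replicate 2. The interferon-stimulated list was higher (median 0.68, camera adjusted p = 0.000451, adjusted p = 0.370 with an estimated correlation), with 3 of 16 genes risen, and with 7 risen and 1 fallen when adjusted over the list alone. The 3 included Ifit2 (1.48 ± 0.37).

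Steroid-responsive genes moved both ways at 48 h. Zbtb16 had the largest fall of all genes that passed the test (-3.72 ± 0.40, adjusted p = 0.00227), and Ddit4 (-1.94 ± 0.25) and Fkbp5 (-1.40 ± 0.26), all 3 glucocorticoid-responsive, also fell, while Glul rose (1.69 ± 0.27). That list had 5 falls and 1 rise among 15 genes (5 and 2 when adjusted over the list alone; camera adjusted p = 0.328). Of 15 progestin-responsive genes Cited1 (-2.69 ± 0.49) and Myc fell and Fgf2 rose (1.45 ± 0.38), the same when adjusted over the list alone (camera adjusted p = 0.964; median 0.14, mean -0.01), and the progesterone receptor gene Pgr stood at 0.13 ± 0.29. Of 20 estrogen-responsive genes 3 rose and 4 fell (5 and 5 when adjusted over the list alone; camera adjusted p = 0.906), with Nrip1 (1.75 ± 0.23) and Igfbp4 (1.85 ± 0.43) among the rises. The RANKL gene Tnfsf11 (0.39 ± 0.28) and Wnt4 (-0.10 ± 0.39) did not pass the test. Growth factors and receptors were not called as a list (camera adjusted p = 0.0994; 5 of 21 rose and 2 fell, 8 and 2 when adjusted over the list alone). The ligand genes Ereg (2.58 ± 0.41) and Hgf (1.58 ± 0.26) rose, and Nrg1 (-2.18 ± 0.44) and the receptor gene Fgfr2 (-1.60 ± 0.31) fell. The apoptosis and p53 target list had 4 rises among 19 genes, also 4 when adjusted over the list alone (camera adjusted p = 0.0529), with Ccng1 (1.45 ± 0.29) and Pmaip1 (1.35 ± 0.27). The milk and secretory list had 3 rises and 1 fall among 16, the same when adjusted over the list alone (camera adjusted p = 0.115). The rises included Plin2 (2.46 ± 0.28) and Cel (4.91 ± 1.42), which the pancreas also makes.

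Heat shock genes had 1 rise and 5 falls among 12 (2 and 5 when adjusted over the list alone; camera adjusted p = 0.205), immediate early genes 3 and 2 among 18, the same when adjusted over the list alone (camera adjusted p = 0.491), and antigen presentation genes 1 and 2 among 15, the same when adjusted over the list alone (camera adjusted p = 0.906). No gene passed in the unfolded protein response list (15 genes, median -0.02, mean 0.11, camera adjusted p = 0.610), the adipocyte list (12 genes, camera adjusted p = 0.243) or the skeletal muscle list (15 genes, median 1.96), also when adjusted over the list alone. The muscle list was called (camera adjusted p = 0.000423, adjusted p = 0.474 with an estimated correlation) with the muscle genes at 3.29 in replicate 1 and 0.21 in replicate 2, and its adjusted p was 0.569 without replicate 1. The largest rises among genes that passed the test with no overlap between the groups' arrays were the exocrine pancreas genes Reg3b (7.13 ± 1.97, adjusted p = 0.0412), Reg2 (7.09 ± 1.65), Ctrb1 (6.93 ± 1.43), Rnase1 (6.88 ± 1.56), Cpb1 (6.83 ± 1.59) and Prss2 (6.68 ± 1.53). Of 20 pancreas genes, a list written after these rises had been seen, 14 passed (camera adjusted p = 2.58e-10, adjusted p = 0.502 with an estimated correlation). After Zbtb16 the largest falls among such genes were Agtr1a, an angiotensin receptor gene (-3.56 ± 0.33), Idi1, the replication kinase gene Cdc7 (-3.19 ± 0.44), Tesc (-3.15 ± 0.30) and the somatostatin receptor gene Sstr3 (-3.14 ± 0.35), all past the threshold.

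In all, 2272 of 18193 genes changed between MFP 48 h and MPA (limma, Benjamini-Hochberg), 1177 up and 1095 down. Fitted on these 4 arrays alone, 43 genes passed. The count was 564 without MPA replicate 1, 1033 without MFP 48 h replicate 1 and 1264 without MFP 48 h replicate 2, and without MPA replicate 2 the split was 1166 up and 689 down.

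**Figure D3:**
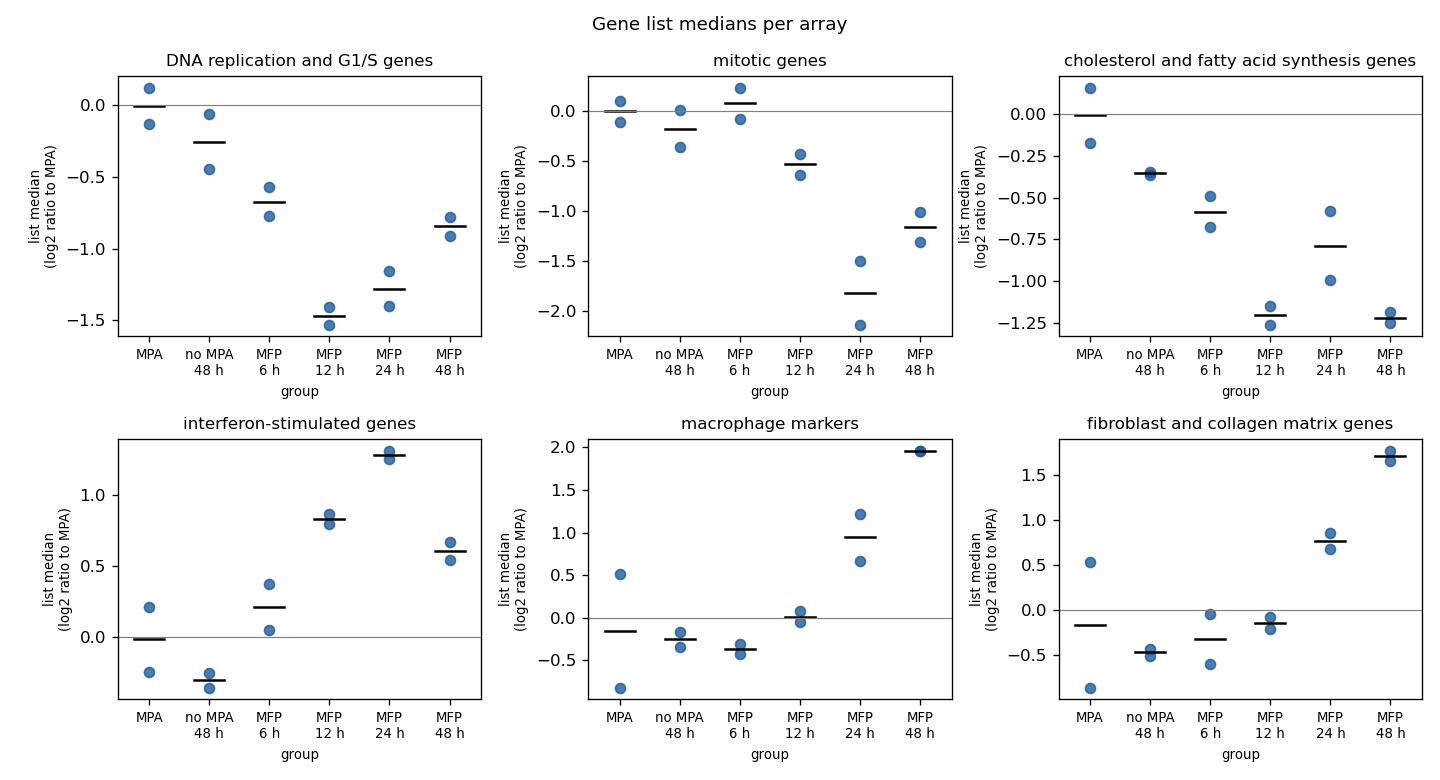
Median log2 ratio to MPA (vertical axes) of 6 gene lists in each group (horizontal axes). Points are single arrays and bars are group means. The DNA replication medians were -1.41 and -1.53 at MFP 12 h and -1.40 and -1.16 at MFP 24 h, the mitotic median was lowest at MFP 24 h, at -2.14 and -1.50, and the macrophage median was highest at MFP 48 h, at 1.96 and 1.95.

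At 24 h of MFP, 21 of 23 mitotic genes were lower than in MPA and none was higher (23 when adjusted over the list alone; median -1.75, camera adjusted p = 1.87e-20, adjusted p = 0.125 with an estimated correlation). Aurkb stood at -3.50 ± 0.21 (adjusted p = 9.03e-05), Mki67 at -2.18 ± 0.40, and Aspm (-3.09 ± 0.39) and Kif2c (-3.29 ± 0.35), which act on the spindle, fell as well. Of 24 DNA replication genes 14 fell (19 when adjusted over the list alone; median -1.17, camera adjusted p = 1.64e-13, adjusted p = 0.125 with an estimated correlation), led by Cdc6 (-3.82 ± 0.44) and Rrm2 (-2.79 ± 0.39). Of 16 interferon-stimulated genes 9 rose and none fell (11 when adjusted over the list alone; median 1.33, camera adjusted p = 1.02e-08, adjusted p = 0.314 with an estimated correlation), including Ifit2 (2.39 ± 0.37) and Ifit1 (1.92 ± 0.27). Macrophage markers had 6 rises among 17 (8 when adjusted over the list alone; median 1.13, camera adjusted p = 2.13e-06, adjusted p = 0.366 with an estimated correlation), including Mpeg1 (1.83 ± 0.34), and fibroblast and matrix genes 4 among 20 (6 when adjusted over the list alone; camera adjusted p = 8.28e-06, adjusted p = 0.366 with an estimated correlation), including Postn (1.96 ± 0.25). The cytotoxic granule gene Gzmb (2.02 ± 0.53) and the chemokine gene Ccl5 (1.91 ± 0.41) were the 2 risen members of the T and NK cell list, also when adjusted over the list alone, and that list was not called (camera adjusted p = 0.11). Esr1 fell (-1.53 ± 0.24), Ccnd1 fell (-1.15 ± 0.24), Rgs2 fell (-3.14 ± 0.20), and Pgr stood at 0.99 ± 0.29 (adjusted p = 0.0623). The fibroblast list median was 0.86 and 0.68 in the MFP 24 h arrays and -0.86 and 0.54 in the MPA arrays, so that the rise was small against MPA replicate 2. That of the macrophage list was 0.66 and 1.22 in the MFP 24 h arrays and -0.82 and 0.52 in the MPA arrays. In the MFP 24 h arrays the liver genes had medians of 3.50 and 3.95 and the Actb 3' minus 5' difference was 0.43 ± 0.11 (SD, n = 2).

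Among genes that passed the test with no overlap between the groups' arrays, the largest rises at 24 h were genes of hepatocytes. These were Hamp (5.99 ± 1.19, adjusted p = 0.0138), Pzp (5.90 ± 1.31), Cyp2e1 (5.67 ± 1.05), Ugt2b34 (5.62 ± 0.55) and Apoc3 (5.57 ± 0.98), and 24 of the 27 liver genes passed. As a list, written after the largest rises had been seen, the liver genes had a camera adjusted p = 1.38e-25, and adjusted p = 0.0842 with an estimated correlation. Members of the fixed lists that the liver also makes rose with them: the acute phase gene Orm1 (4.69 ± 0.75) among 7 risen involution genes of 20, also 7 when adjusted over the list alone; Pck1 (4.08 ± 0.55) and Thrsp (2.95 ± 0.47) among 3 risen adipocyte genes of 12, or 5 when adjusted over the list alone; and Igf1 (3.61 ± 0.39), Egfr (1.81 ± 0.39) and Igfbp1 (3.05 ± 0.72). With an estimated correlation the involution list had an adjusted p = 0.306 and the adipocyte list an adjusted p = 0.329. The B and plasma cell list was higher (median 1.42, camera adjusted p = 0.0133, adjusted p = 0.519 with an estimated correlation) with no gene past the threshold, also when adjusted over the list alone. Its camera adjusted p was 0.988 without MFP 24 h replicate 2 and 0.0754 without MPA replicate 1, and that of the adipocyte list was 0.0644 without MFP 24 h replicate 2. In all 1591 genes changed at 24 h, 827 up and 764 down. Leaving out the 490 genes whose values over the 12 arrays followed the liver, pancreas or muscle genes with a correlation above 0.8, an alternative chosen after seeing the data, gave 1229, with 509 up and 720 down. As the liver genes are high at 24 h, genes that rise then tend to follow them whatever their source. All 283 changed genes left out were rises, so the lower share of rises follows from this choice of genes. Fitted on the 4 arrays alone 117 genes passed, with array weights 980, without MPA replicate 1 751 and without MFP 24 h replicate 2 687. The split was 883 up and 458 down without MPA replicate 2, and 1003 up and 607 down without MFP 24 h replicate 1.

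At 12 h of MFP the DNA replication genes were lower than in MPA in 15 of 24 cases, with none higher (20 when adjusted over the list alone; median -1.36, camera adjusted p = 1.71e-20, adjusted p = 0.0889 with an estimated correlation). Cdc6 stood at -3.68 ± 0.44 and Rrm2, a subunit of ribonucleotide reductase, at -3.01 ± 0.39 (adjusted p = 0.00698). Only 2 of 23 mitotic genes fell, also when adjusted over the list alone (median -0.50, camera adjusted p = 0.00033, adjusted p = 0.642 with an estimated correlation). The step from 12 h to 24 h, a contrast added after seeing the data, had a median of -1.23 in the mitotic list with 8 falls (camera adjusted p = 5.01e-18, adjusted p = 0.312 with an estimated correlation). For the same step the DNA replication list had a median of 0.14, with no gene past the threshold, and was not called (camera adjusted p = 0.209). Of 17 cholesterol and fatty acid genes 8 fell (13 fell and 1 rose when adjusted over the list alone; camera adjusted p = 2.16e-09, adjusted p = 0.111 with an estimated correlation), with Idi1 at -4.03 ± 0.43 and Elovl6 at -2.86 ± 0.49. The nucleotide synthesis enzyme genes Cad (-3.15 ± 0.51) and Ppat (-3.08 ± 0.57) were among the largest falls. Of 16 interferon-stimulated genes 5 rose (8 when adjusted over the list alone; camera adjusted p = 6.13e-08, adjusted p = 0.370 with an estimated correlation), including Gbp2 (1.68 ± 0.34). Luminal markers had 4 rises among 17 (5 when adjusted over the list alone; camera adjusted p = 9.02e-05, adjusted p = 0.571 with an estimated correlation), including Cldn4 (1.56 ± 0.23) and Pgr (1.44 ± 0.29, adjusted p = 0.0239). Ccnd1 (-1.47 ± 0.24), Myc (-1.73 ± 0.29), Fkbp5 (-1.32 ± 0.26) and Nrg1 (-2.88 ± 0.44) fell, and Esr1 stood at -0.28 ± 0.24. Large rises included Ceacam1 (3.05 ± 0.45), Ido1, an enzyme of tryptophan breakdown (2.90 ± 0.66), and Mal (2.83 ± 0.33). The Actb 3' minus 5' difference at this time was 0.35 ± 0.02 (SD, n = 2).

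In all 778 genes changed at 12 h, 302 up and 476 down, and none passed in a fit of the 4 arrays alone. The count was 293 without MPA replicate 1, 359 without MPA replicate 2, where rises outnumbered falls, with 189 up and 170 down, and 115 and 56 without MFP 12 h replicate 1 and 2.

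At 6 h of MFP, Ccnd1, which encodes cyclin D1 (-1.85 ± 0.24, adjusted p = 0.0132), Myc (-1.70 ± 0.29) and the ERBB receptor ligand gene Nrg1 (-2.58 ± 0.44) were already lower than in MPA. Grwd1, a gene of ribosome assembly, had the largest fall among genes that passed the test with no overlap between the groups' arrays (-3.24 ± 0.21, adjusted p = 0.000319). The chaperone genes Hspd1 (-1.56 ± 0.24) and Hsph1 (-1.74 ± 0.30) fell. Of the DNA replication genes 1 of 24 passed, Mcm2 (-1.25 ± 0.20), also 1 when adjusted over the list alone, and the list median was -0.68 (camera adjusted p = 2.92e-08, adjusted p = 0.664 with an estimated correlation). No mitotic gene passed, also when adjusted over the list alone (median 0.10, camera adjusted p = 0.562). Mal (1.83 ± 0.33), Clmn (1.78 ± 0.30) and Plet1 (1.74 ± 0.34) rose, as did the interferon-stimulated gene Oasl2 (1.10 ± 0.19). Among genes that passed the test with no overlap between the groups' arrays, the pancreas gene Ctrb1 had the largest rise (6.98 ± 1.43), in arrays with pancreas medians of 5.73 and 4.24. Only 1 of 20 pancreas genes passed at this time. Pgr (0.78 ± 0.29) and Mki67 (0.07 ± 0.40) did not pass.

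In all 228 genes changed at 6 h, 57 up and 171 down, and none passed in a fit of the 4 arrays alone. The count was 68 and 5 without MPA replicate 1 and 2, and 2 and 1 without MFP 6 h replicate 1 and 2, so that single arrays decided it.

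Averaged over the 4 MFP times, 1381 genes differed from MPA, 527 up and 854 down. Cdc6 (-2.97 ± 0.35), Idi1 (-2.74 ± 0.34), Cdc7 (-2.67 ± 0.35), Zbtb16 (-2.60 ± 0.32) and Nrg1 (-2.55 ± 0.35) had the largest falls among genes past the threshold with no overlap between the groups' arrays. Besides pancreas genes such as Reg2 (5.13 ± 1.30), large rises were seen in Clca3a2 (2.84 ± 0.68), Mal (2.45 ± 0.26), Ctse (2.42 ± 0.61), Clca3a1 (2.33 ± 0.33) and the keratin gene Krt4 (2.32 ± 0.33), which secretory or stratified epithelia express. Of 24 DNA replication genes 14 fell (21 when adjusted over the list alone; camera adjusted p = 4.09e-16, adjusted p = 0.158 with an estimated correlation). The count was 1022 without the MFP 24 h arrays, an alternative chosen after seeing the data, 852 with array weights, 221 without MPA replicate 1, 895 without MFP 12 h replicate 2, and 795 without MPA replicate 2, where rises outnumbered falls, with 478 up and 317 down.

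The comparison of no MPA with MPA tumours had no gene past the threshold in limma, against 1198 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.114, shared by several genes, among them Pgr, at 2.21 ± 0.29, and the signalling gene Stat5a, at 1.54 ± 0.22, both higher in each array than in either MPA array. Adjusted over the list alone, Pgr passed among 17 luminal markers and Stat5a among 15 progestin-responsive genes. In the same way 2 of 15 glucocorticoid-responsive genes and 1 of 18 immediate early genes were higher and 1 of 12 heat shock genes was lower. None of these 5 lists was called. Of 20 estrogen-responsive genes, again with Pgr, 3 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.581 with an estimated correlation), and of 17 cholesterol and fatty acid genes 1 was higher and 3 were lower (camera adjusted p = 0.00824, adjusted p = 0.655 with an estimated correlation). The interferon-stimulated list had a median of -0.36 (camera adjusted p = 0.0108, adjusted p = 0.655 with an estimated correlation) and no gene past the threshold, also when adjusted over the list alone. Ccnd1 (-0.03 ± 0.24), Mki67 (-0.24 ± 0.40) and Esr1 (-0.70 ± 0.24) did not pass. The DNA replication list had a median of -0.21 (camera adjusted p = 0.0233, adjusted p = 0.655 with an estimated correlation), with no gene past the threshold, also when adjusted over the list alone. Without MPA replicate 1, 4 genes passed, and the camera adjusted p was 0.200 for the cholesterol list and 0.113 for the estrogen list. Without MPA replicate 2 it was 0.307 for DNA replication and 0.811 for interferon-stimulated genes, without no MPA replicate 1 0.251 for the estrogen list, and without no MPA replicate 2 0.508 for DNA replication. In simulated data with changes of known size planted between MFP 48 h and MPA, 20.8% of changes of 1 on the log2 scale and 91.8% of changes of 2 were recovered. No change was planted between no MPA and MPA, and the share recovered depends on how many genes change. These shares therefore do not say how many changes would be found without MPA, where Pgr at 2.21 did not pass.

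Against no MPA, the tumours at 48 h of MFP had 1362 genes up and 915 down, 2277 in all. Macrophage markers rose in 16 of 17 cases (17 when adjusted over the list alone; median 2.36, camera adjusted p = 9.92e-16, adjusted p = 0.136 with an estimated correlation), with Msr1 at 4.04 ± 0.62 and Mrc1 at 3.26 ± 0.59. Fibroblast and matrix genes rose in 16 of 20 cases (19 when adjusted over the list alone; median 2.03, camera adjusted p = 9.92e-16, adjusted p = 0.136 with an estimated correlation), with Col3a1 at 3.28 ± 0.52 and Lox, a collagen crosslinking enzyme, at 3.12 ± 0.62. Mitotic genes fell in 10 of 23 cases (13 when adjusted over the list alone; median -0.98, camera adjusted p = 1.97e-09, adjusted p = 0.136 with an estimated correlation) and luminal markers in 7 of 17 (9 fell and 3 rose when adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.459 with an estimated correlation). Pgr (-2.08 ± 0.29, adjusted p = 0.00282), Stat5a (-1.84 ± 0.22), Esr1 (-1.02 ± 0.24) and Gata3 (-2.52 ± 0.46) fell, as did Tfap2b (-3.62 ± 0.45) and Nrxn3 (-3.41 ± 0.60). Timp1 (4.17 ± 0.58), Ereg (3.07 ± 0.41) and Cdkn1a (1.11 ± 0.23) rose. The Actb 3' minus 5' difference was 0.53 ± 0.09 at MFP 48 h and 0.02 ± 0.16 in no MPA (SD, n = 2). Of 20 exocrine pancreas genes 16 also rose (median 5.75), and the muscle list was called (median 1.48, camera adjusted p = 0.00405, adjusted p = 0.513 with an estimated correlation). Its adjusted p was 0.571, in the other direction, without MFP 48 h replicate 1 and 0.0510 without no MPA replicate 2. The count was 746 and 984 without no MPA replicate 1 and 2, and 1164 without MFP 48 h replicate 1. The camera adjusted p of the luminal list was 0.0655 without no MPA replicate 1 and 0.0961 without MFP 48 h replicate 1.

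Within the 8 MFP arrays, 2036 genes had a slope over the logarithm of time from 6 h to 48 h, 1238 rising and 798 falling. Slopes are given per doubling of time. Macrophage markers rose in 15 of 17 cases (16 when adjusted over the list alone; median slope 0.78, camera adjusted p = 6.75e-19, adjusted p = 0.124 with an estimated correlation), with Msr1 at 1.35 ± 0.08 and Cd68 at 1.06 ± 0.09. Fibroblast and matrix genes rose in 18 of 20 (19 when adjusted over the list alone; median 0.72, camera adjusted p = 1.25e-18, adjusted p = 0.183 with an estimated correlation), with Lox at 1.15 ± 0.15. The myeloid genes Ccl6 (1.57 ± 0.23), F13a1 (1.52 ± 0.16), Ccr1 (1.40 ± 0.13) and Clec4d (1.36 ± 0.11) had some of the steepest rises. Mitotic genes fell in 9 of 23 cases (17 when adjusted over the list alone; median -0.49, camera adjusted p = 6.20e-10, adjusted p = 0.426 with an estimated correlation), and hypoxia and glycolysis genes in 8 of 16 (10 when adjusted over the list alone; camera adjusted p = 5.76e-06, adjusted p = 0.436 with an estimated correlation). From 24 h to 48 h, a contrast added after seeing the data, the mitotic list was higher (median 0.49, camera adjusted p = 2.55e-06, adjusted p = 0.431 with an estimated correlation), with 1 gene past the threshold. The DNA replication list was higher as well (median 0.44, camera adjusted p = 0.000707, adjusted p = 0.431 with an estimated correlation), also with 1 gene. Gata3 (-0.99 ± 0.16), Esr1 (-0.67 ± 0.09), Nrxn3 (-1.24 ± 0.16) and Tfap2b (-1.18 ± 0.14) fell with time. Ccnd1 rose (0.43 ± 0.06, adjusted p = 0.00329) from its low value at 6 h. The Actb 3' minus 5' difference also rose over these times, from 0.16 ± 0.05 to 0.53 ± 0.09 (SD, n = 2). The count was 1326 and 1211 without MFP 6 h replicate 1 and 2, and 1186 and 1207 without MFP 48 h replicate 1 and 2.

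No gene was shared between the changes at MFP 48 h and those without MPA, both against MPA, because the second comparison had none, and 0 were expected from independent lists. Over all genes the fold changes of these comparisons correlated at 0.163 across genes, which are not independent replicates. In 100 simulations of unchanged groups against shared simulated MPA arrays the correlation averaged 0.499. The covariance was 0.0449, against 0.0546 (SD 0.0019) in the simulations. The simulated genes varied independently and held no change, while 2272 genes changed at MFP 48 h. The correlations are therefore not compared like with like, and the SD leaves out variation that genes share. With 1 MPA array for each comparison, so that none was shared, an alternative chosen after seeing the data, the correlation was -0.242 with MPA replicate 1 for MFP 48 h and replicate 2 for no MPA. It was 0.0931 the other way round.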

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

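All tests of explanations in this part were chosen after the results had been seen; the slopes were planned. Gene lists and genes changed differently at different MFP times, by a test of the slope over time. The median slope per doubling of time was 0.78 for macrophage markers, 0.72 for fibroblast and collagen matrix genes, 0.65 for neutrophil markers, 0.53 for skeletal muscle markers, 0.50 for mammary involution genes, 0.22 for endothelial markers and 0.19 for basal and myoepithelial markers. It was -0.49 for mitotic genes, -0.33 for hypoxia and glycolysis genes, -0.24 for luminal epithelial markers and -0.17 for cholesterol and fatty acid synthesis genes. None of these lists was called with an estimated correlation. The muscle slope rests on MFP 48 h replicate 1, without which its camera adjusted p was 0.821, and that of the cholesterol list was 0.0629 and 0.0567 without MFP 6 h replicate 1 and 2 and 0.0776 without MFP 48 h replicate 1. Among the genes named in every comparison the slope was 0.43 for Ccnd1, -0.69 for Mki67 and -0.67 for Esr1.

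Control probe sets outside the comparisons lay above the MPA arrays in every MFP array of a group: the 3' minus 5' difference of Actb averaged 0.16 at 6 h, 0.35 at 12 h, 0.43 at 24 h and 0.53 at 48 h, and that of Gapdh 0.28 at 12 h, 0.49 at 24 h and 0.42 at 48 h. The 3' minus 5' difference of the 18S rRNA controls went the other way, at 0.02 and -0.02 in the MPA arrays and between -0.15 and -0.06 in the MFP arrays. It was also lower in both no MPA arrays, at -0.06. For the time trend, 100 arrangements of the times over the 8 arrays were counted, the real one included. The real one gave 2036 genes, the highest other 1441, and only 1 arrangement, the real one, gave as many. The count is thus rare among random orders of these arrays. The draws treat the 8 arrays as separate samples, which no label states, and they split the arrays of a time. Any difference between the times lowers the count in such draws, and the median of the others was 0. Orders of whole times were not compared. The rarity therefore does not show by itself that genes follow the order of the times. The draws also do not tell what the slopes come from.

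Genes of liver and pancreas were high in some arrays. Of 22 liver genes that were not among the named largest rises, 21 were over 2-fold higher in both MFP 24 h arrays than in both MFP 12 h arrays. RNA of liver tissue in the 24 h samples would give this, but so would any other cause of a joint rise of liver genes. As the list was written after that rise had been seen, the count does not tell these causes apart. Alb stood at 3.33 and 3.51, Apoa1 at 3.77 and 4.26 and Ttr at 3.50 and 3.95 in those arrays. A rise of the pancreas genes through MFP that is alike in all samples of a time is argued against by the MFP 24 h arrays. The median difference between them was 5.71, above the largest of any fixed list, 2.55. The pancreas list was written after its large changes had been seen, so passing that bound does not tell causes apart. A response to MFP that differs between samples is not excluded. The liver genes also differed by 2.33 between the MPA arrays, neither given MFP, but a rise through MFP on top of this cannot be told apart from tissue carried over, because both 24 h arrays are alike; tissue from other organs in the blocks may be the source, and no label speaks of it.

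The DNA replication and mitotic lists fell while the 3' bias of Actb and Gapdh, though not of 18S rRNA, rose. Loss of RNA integrity as the whole cause of the DNA replication fall is argued against by the times. The list mean was higher by 0.57 ± 0.02 (SE) at 48 h than at 12 h, while the Actb difference was higher at 48 h. Each SE here and in the next paragraph comes from the list means of 2 arrays per group, without limma's shared spread. Such an SE is itself imprecise: the 12 h means had an SD of 0.0069. The luminal list gave no sign of a smaller share of tumour cells at 12 h, as its mean was higher than in MPA by 0.57 ± 0.04 (SE). Its members include genes that rose themselves, such as Cldn4 and Pgr, the latter at 1.46 and 1.40 in the 12 h arrays. The list is therefore no fixed gauge of that share, which is not settled. A part played by RNA integrity in the mitotic fall stays open, as does a response to MFP, which the design names. A response to the removal of MPA, which came with MFP, stays open at 6 h, 12 h and 24 h. At these times it cannot be told apart from a response to MFP, as the no MPA group is at 48 h. At 48 h the mitotic list means were -0.36 and -0.01 in no MPA, against -1.14 and -1.35 with MFP. The DNA replication list means were -0.12 and -0.44, against -0.91 and -0.95. In MPA the means were -0.15 and 0.11 for mitotic and -0.14 and 0.10 for DNA replication genes. If the no MPA label holds, the values argue against removal of MPA as the whole cause at 48 h. Its part there stays open.

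Macrophage and fibroblast lists rose at MFP 48 h. A smaller share of tumour cells alone would raise the lists of other cell types alike if their genes lay equally far above background, which ratios cannot show. The mean change of the macrophage list exceeded that of the endothelial list by 1.46 ± 0.44 (SE). This weighs against that sole cause only on this condition, and the fibroblast list was not compared in this way. The luminal list means were -0.68 and -0.17 at 48 h and -0.01 in both MPA arrays, so a smaller share stays open. Macrophages brought in with pancreas tissue are argued against by MFP 6 h, where the pancreas genes were about as high and the macrophage list mean differed from MPA by -0.23 ± 0.69 (SE), against 2.13 at 48 h. More macrophages, a change in the state of those present, and other tissue in the blocks stay open, and a response to MFP may be among the causes.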

How the results depend on the processing

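Leaving out each array, single probe sets, centring, fits of the compared groups, array weights and the estimated correlation were chosen before the data were examined, and the mean of a gene's probe sets, the genes with an SD above the median, the robust prior, the omission of organ-following genes and the omission of the MFP 24 h arrays after seeing them. No paired analysis was possible because the replicate numbers carry no link between groups. A filter on log2 values above 5, a stricter one, the highest-mean probe set, quantile normalization between arrays and a variance trend with level were not run, because the deposited ratios hold no level and the spread of the MPA columns is narrowed by the division; the same loss leaves signal over background unknown, so that genes near background cannot be set apart. All genes were kept, so that a comparison without a filter is the one reported. With centring, counts stayed within 1.5 times those reported, as they did with the robust prior and without the 490 organ-following genes, though at MFP 24 h the share of risen genes went from 52.0% to 41.4%, which follows from the choice of genes, since all 283 changed genes left out there were rises. Of 502 values for named genes, centring left 489 on their side of the threshold, array weights 464, the robust prior 487 and the mean of probe sets 456. Fits of the compared groups left 243 of 422, and leaving out 1 array 1965 of 2694, with 712 no longer passing.

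Tests of every probe set counted probe sets rather than genes and gave 4166 at MFP 48 h, 2708 at 24 h, 1409 at 12 h, 417 at 6 h, 2518 for the mean, 4212 against no MPA and 4180 for the time trend. With the compared groups alone, which leaves fewer degrees of freedom, the counts were 43 at 48 h, 117 at 24 h, 0 at 12 h and 0 at 6 h, and with array weights 980 at 24 h and 852 for the mean; the cause was not tested. With the genes of larger SD 90 genes passed at 6 h, fewer genes being tested. With an estimated correlation 0 lists were called at 48 h, 0 at 24 h, 0 at 12 h, 0 at 6 h, 0 for the mean, 0 for no MPA, 0 for MFP 48 h against no MPA and 0 for the trend, the estimated correlation exceeding the preset 0.01 in each list called with the preset, apart from the estrogen-responsive list for no MPA. With the mean of probe sets 9 lists were called for no MPA, against 4, and H2-D1 at 48 h stood at 0.16 against -0.87, since its probe sets disagree.

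When 1 array is left out, the lone array of its group is assumed to vary like the other groups. The count then ranged from 564 (without MPA replicate 1) to 1855 at MFP 48 h, from 687 (without MFP 24 h replicate 2) to 1610 at 24 h, from 56 (without MFP 12 h replicate 2) to 359 at 12 h, from 1 (without MFP 6 h replicate 2) to 68 at 6 h, from 221 (without MPA replicate 1) to 1467 for the mean, from 0 to 4 for no MPA, from 746 (without no MPA replicate 1) to 1539 against no MPA, and from 1186 (without MFP 48 h replicate 1) to 1914 for the trend; the overlap ranged from 0 to 1. With 1 MPA array for each comparison, also chosen after seeing the data, the correlation of fold changes across genes was -0.242 and 0.0931, against 0.163, no control then being shared. Lists called numbered 14 to 15 at 48 h, 10 to 18 at 24 h, 6 to 13 at 12 h, 4 to 10 at 6 h, 9 to 15 for the mean, 4 to 9 for no MPA, 15 to 16 against no MPA and 10 to 14 for the trend. Some lists turned direction, with these ranges of the camera adjusted p. At 6 h all turned without MPA replicate 2: involution 0.0307 to 0.987 (0.0495 there), fibroblast 8.67e-06 to 0.987 (0.0125), macrophage 3.49e-08 to 0.564 (0.000948) and hypoxia 0.0163 to 0.215 (0.0404). At 12 h macrophage (2.69e-07 to 0.942) and hypoxia (0.0233 to 0.961) turned without MPA replicate 1, at 0.00105 and 0.0492, and fibroblast (0.000677 to 0.942) without MPA replicate 2. For no MPA, fibroblast (8.55e-09 to 0.240) and macrophage (8.06e-11 to 0.461) turned without MPA replicate 2, at 0.0428 and 0.000112. The B and plasma cell list at 24 h (6.51e-07 to 0.988) turned without MFP 24 h replicate 2, and the muscle list of MFP 48 h against no MPA (6.44e-14 to 0.571) without MFP 48 h replicate 1. The macrophage medians of the MPA arrays were -0.82 and 0.52. Those at MFP 6 h (-0.31 and -0.43), at 12 h (0.08 and -0.05) and in no MPA (-0.34 and -0.16) lay between them. The direction of the macrophage list there thus depends on which MPA array is kept. Why the MPA arrays differ, and the cause of the other turns, was not tested.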

Other observations

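The tests of this part were chosen after the largest changes had been seen. Genes of ribosome biogenesis were lower at 6 h, 12 h and 24 h of MFP, with an adjusted p of 0.0030, 0.00505 and 0.0487 with an estimated correlation, and at 48 h their call was lost with it (adjusted p = 0.0979). At 6 h, 11 of 32 measured genes fell and none rose (median -1.19), among them the nucleolar genes Dkc1 (-1.99 ± 0.21), Nop56 (-1.86 ± 0.23), Gnl3 (-1.76 ± 0.19), Ddx21 (-1.89 ± 0.25) and Nolc1 (-2.25 ± 0.36). The number was 15 at 12 h (median -0.90), 11 at 24 h (median -0.67) and 8 at 48 h (median -0.68), and none at no MPA (median 0.03). Per array the median was -1.12 and -1.46 at 6 h and between -0.97 and -0.54 at the later times. Genes of nucleotide synthesis had 3 falls among 17 at 6 h, 7 at 12 h (median -1.02), 6 at 24 h and 2 at 48 h, with an adjusted p of 0.0114, 0.00505, 0.0601 and 0.259 at these times with an estimated correlation. These lists were picked because Grwd1, Cad and Ppat had been seen among the largest falls. Grwd1 is in neither list, while Cad and Ppat are members of the second, so that its test is not independent of them.

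The camera tests were adjusted over these lists, the organ lists and the muscle list fixed before. As the lists were written after falls of this kind had been seen, the tests describe these data and are no independent evidence for the class.

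The liver list was also called at 6 h (median 0.69, adjusted p = 0.0151, adjusted p = 0.838 with an estimated correlation), at 12 h (median -0.71, adjusted p = 0.0144, adjusted p = 0.924 with an estimated correlation), for the mean of the MFP times (median 1.04, adjusted p = 2.17e-05, adjusted p = 0.693 with an estimated correlation), for no MPA against MPA (median -0.73, adjusted p = 3.14e-05, adjusted p = 0.907 with an estimated correlation) and for MFP 48 h against no MPA (median 0.71, adjusted p = 0.0245, adjusted p = 0.863 with an estimated correlation). The pancreas list was also called at 6 h (median 5.32, adjusted p = 4.59e-17, adjusted p = 0.254 with an estimated correlation), at 24 h (median 4.05, adjusted p = 1.05e-08, adjusted p = 0.392 with an estimated correlation), for the mean (median 3.91, adjusted p = 8.10e-11, adjusted p = 0.490 with an estimated correlation) and for MFP 48 h against no MPA (median 5.75, adjusted p = 8.84e-12, adjusted p = 0.318 with an estimated correlation). In the comparison of MFP 24 h with MPA, the median was 0.57 for 8 islet genes, -0.21 for 11 kidney genes, -0.03 for 11 intestine genes, -0.10 for 10 epidermis genes, -0.05 for 10 heart genes and 0.74 for 9 brain genes, and none of these lists was called; 2 intestine genes rose and 1 heart gene fell. The islet gene Gcg stood at 4.99 in MFP 24 h replicate 2 and at 0.06 in replicate 1. The brain list was called at 6 h and 12 h (adjusted p = 0.0457 and 0.0467, adjusted p = 0.792 and 0.924 with an estimated correlation) with no gene past the threshold. Its median was 0.52 in both MFP 6 h arrays. It was 1.22 in MFP 12 h replicate 1 and 0.05 in replicate 2. At 24 h, where the list was not called, it was 0.02 in replicate 1 and 1.46 in replicate 2. Single arrays thus stand apart at 12 h and 24 h, but not at 6 h. The epidermis list was called for no MPA against MPA (median 0.39, adjusted p = 0.000248, adjusted p = 0.251 with an estimated correlation), again with no gene past the threshold, and for MFP 48 h against no MPA, where 3 of 10 genes fell (median -0.33, adjusted p = 0.0245, adjusted p = 0.318 with an estimated correlation).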
